A study of Mus musculus with 12 samples.

How the data were processed

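The data are gene expression profiles of whole mouse lung, made on Affymetrix arrays from biotin-labelled cRNA, with 12 arrays in 4 groups of 3. Mice carried floxed Nfat5 alleles. NFAT5 is a transcription factor best known for switching on genes that protect cells from high salt. Per the labels' protocols, its gene was deleted in endothelial cells of adult males and females aged 10 to 12 weeks with 1 mg of tamoxifen daily for 5 days, and control mice received only the solvent miglyol. Mice recovered for 2 to 3 weeks and were then kept in normoxia or in hypoxia for 21 days. Lungs were perfused with cold Ringer solution to wash out blood, and lung tissue was lysed for RNA. Because the knockout mice received tamoxifen and the controls did not, the deletion and the drug cannot be told apart in these groups.

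The series' design text gives 4 mice per group, while 3 arrays per group were analysed here. Replicate numbers 1, 2 and 4 were used in 3 of the groups and 2, 3 and 4 in the hypoxic knockouts. The same text says that the authors left out preparations with contaminating tissue such as thymus, and those whose expression response to hypoxia was inadequate. The hypoxia comparisons therefore rest on animals chosen in part on the outcome they measure. Replicates are taken to be separate mice, as the design text counts mice.

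The authors deposited normalized log2 expression values, 1 per probe set and array. Per the submitters' processing notes the values were made with RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a gene. Its version, the probe annotation and any filter are not given in the sources used here. The 25428 probe sets held values from 2.41 to 13.7 on the log2 scale. The sorted values of the 12 arrays differed by 0 at every rank, so the arrays had already been brought to 1 distribution, with a median of 4.55 each. A change in total RNA per cell cannot be seen in such values, and a change in 1 large class of transcripts shifts the others.

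Probe sets were named through the platform annotation. A single gene symbol was paired with 24705 probe sets and none with 723, while 0 had several. Of the genes tested, 24673 were found by their Entrez number in a gene table of the GRCm38 assembly, and 0 symbols changed through it. That table was used for names only, and no coordinates are given because the value table names no genome build. Where a symbol had more than 1 probe set, the one with the highest mean was kept, which left out 1 and gave 24704 genes. No filter on low values was used.

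Each gene was fitted with limma 3.58.1 in R 4.3.3 as 4 group means with 8 residual degrees of freedom and empirical Bayes moderation (prior degrees of freedom 3.61, no trend). There were 7 contrasts. They were hypoxia minus normoxia in control, in knockout and averaged over both genotypes, knockout minus control in normoxia, in hypoxia and averaged over both oxygen states, and the interaction, which is the hypoxia contrast in knockout minus that in control. Tests were two-sided. Benjamini-Hochberg adjusted p-values were taken over the 24704 genes within each contrast, and a gene was called at an adjusted p under 0.05. Every adjusted p given for a gene comes from limma. Errors given with log2 changes are limma's standard errors unless called SD.

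Before the data were examined, 60 gene lists with 1091 members were fixed, of which 1013 members were measured. There were 28 pathway lists, 31 cell type lists and 1 of Y-linked genes used only to follow the sex of the animals. The 59 others, each with at least 5 measured members, were tested with limma's camera at a preset correlation between genes of 0.01. Camera asks whether a list's genes move against all other genes, and its p-values were adjusted over the 59 lists in each contrast. Camera with a correlation estimated from the data, camera on ranks, and fry, which asks whether a list's genes move 1 way on balance without regard to other genes, were alternatives. No list call in any of the 7 contrasts held with the estimated correlation, so the p-value from that setting is given with each list. Numbers of members that rose or fell are given at an adjusted p under 0.05 over all genes and also adjusted over the list alone.

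Genes named in the text followed a rule fixed in advance. For each contrast it took the 8 largest increases and the 8 largest decreases among called genes whose arrays did not overlap between the groups (in at least 1 genotype or oxygen state for the averaged contrasts, with no such condition for the interaction), leaving out placeholder symbols. Where none passed it took the 5 smallest unadjusted p-values in each direction. It added up to 4 members with the smallest adjusted p from each list described. Nfat5 was always named, and Pdgfb, Edn1, Bmpr2, Vegfa and Slc2a1 could be named whatever their values. A few genes named outside the rule are marked as chosen after their values were seen.

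Other planned settings were a trended and robust variance model, removal of genes under the 30th percentile of mean level (log2 3.45), all probe sets in place of named genes, array weights, the replicate number as a block, the mean of the Y-linked genes as a covariate, fits on only the groups compared, an adjusted p under 0.10, and leaving out each array in turn. Settings chosen after seeing the data were the mean of 10 nuclear noncoding RNAs as a covariate, Malat1 and Neat1 alone as that covariate, the clock genes Dbp minus Arntl as a covariate, and the removal of the 2 arrays with the highest Ucp1. The nuclear covariate was the array mean of Malat1, Neat1, Kcnq1ot1, Meg3, Tug1, Miat, Pvt1, Airn, Firre and Rian.

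The fits were tested on simulated data for 24704 genes with 200 changed genes. At a log2 change of 1, 91.0% of changed genes were recovered for hypoxia in control, 92.5% for hypoxia in knockout, 97.0% for knockout in normoxia, 91.5% for knockout in hypoxia and 82.0% for the interaction. At a log2 change of 0.5 the shares were 19.0%, 17.0%, 26.5%, 22.5% and 0%. With 3 arrays per group the number of arrays limits the precision. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1.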

Results

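Expression in whole lung was measured in 4 groups of 3 mice. Control mice carried floxed Nfat5 and received solvent, and knockout mice had lost Nfat5 in endothelial cells after tamoxifen. Each genotype was kept in normoxia or in hypoxia for 21 days, an exposure used in mice to bring about thickening of small lung arteries and pulmonary hypertension. The comparisons ask how chronic hypoxia changes the lung transcriptome and whether endothelial NFAT5 alters that response. Arrays of the same group correlated with r between 0.989 and 0.994. The median gene's SD among the 3 arrays of a group was between 0.12 and 0.14 on the log2 scale.

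Nfat5 RNA in normoxia was 9.11 ± 0.25 (SD, n = 3) on the log2 scale in control lungs and 8.67 ± 0.11 in knockout lungs. In hypoxia it was 8.43 ± 0.24 in control and 8.34 ± 0.15 in knockout lungs. The log2 difference between knockout and control lungs in normoxia was -0.44 ± 0.15 (SE; adjusted p = 0.62). The 3 knockout arrays lay below the 3 control arrays, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. In hypoxia the difference was -0.08 ± 0.15, with an exact p of 0.6. Averaged over both oxygen states it was -0.26 ± 0.10 (adjusted p = 1.00), with an exact p of 0.06 over 400 regroupings within oxygen states. Nfat5 fell with hypoxia in control lungs by 0.68 on the log2 scale (adjusted p = 0.016), and the change in knockout lungs was -0.33 ± 0.15 (adjusted p = 0.38). The control value was -0.54 without control normoxia 2 (adjusted p = 0.059) and -0.55 without control hypoxia 2 (adjusted p = 0.067). Over both genotypes Nfat5 fell by 0.50 (adjusted p = 0.0091). The interaction, the difference between these changes, was 0.35 ± 0.21 (adjusted p = 0.68). Lung keeps the Nfat5 RNA of all its other cells, and where the probes lie relative to the deleted part is not given in the sources used here, so this level is a weak check of the labels.

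The level of Nfat5 moved with RNAs that stay in the nucleus. The mean of 10 nuclear noncoding RNAs was 6.54 ± 0.20 in control normoxia, 5.77 ± 0.17 in control hypoxia, 6.21 ± 0.22 in knockout normoxia and 6.0 ± 0.23 in knockout hypoxia (log2, SD). The set was chosen after seeing the data. In control lungs 6 of the 10 fell with hypoxia, among them Neat1, a scaffold of nuclear paraspeckles, by 1.80, and Malat1, a nuclear speckle RNA, by 0.96 on the log2 scale. None of the 10 passed in knockout lungs, where Neat1 changed by -0.69 ± 0.27 (adjusted p = 0.30), and the interaction for Neat1 was 1.11 (adjusted p = 0.57). Within groups, Nfat5 and the nuclear mean were correlated across the 12 arrays with r = 0.866 and rho = 0.853. The exact permutation p was 0.00077 for each, the smallest of 1296 reorderings within groups, and r was 0.823 without the 2 arrays farthest from the median. The relation was chosen after seeing the data, so these p-values cannot be read as those of a planned test. With the nuclear mean as a covariate, the change of Nfat5 with hypoxia was -0.05 in control lungs and -0.11 over both genotypes, and neither passed.

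**Figure D1:**
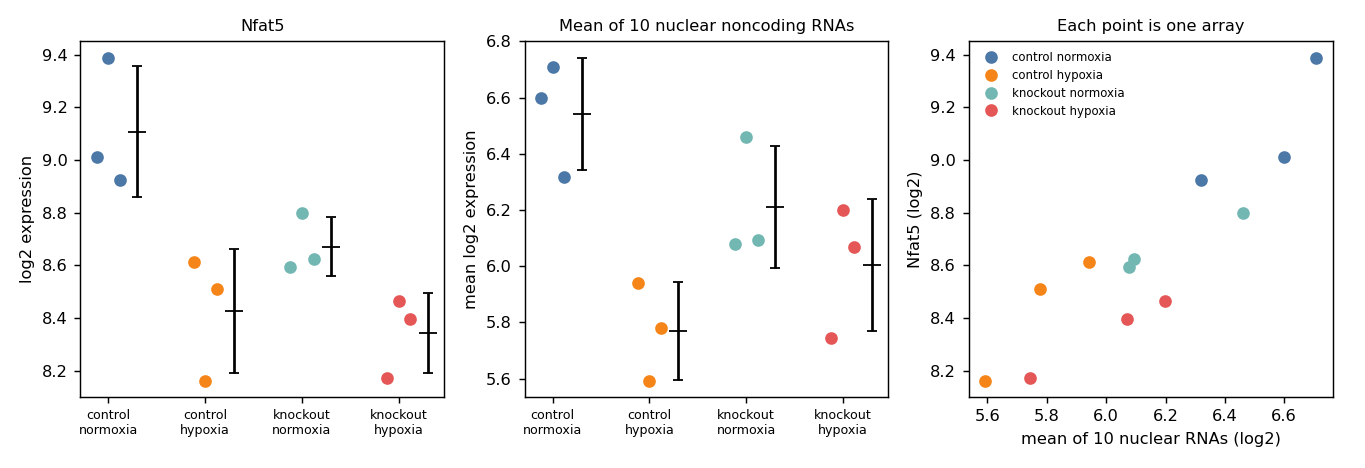
Nfat5 (log2) and the mean of 10 nuclear noncoding RNAs (log2) in the 4 groups, 1 point per array with the group mean and SD beside it, and the 2 measures plotted against each other. Both are highest in control normoxia, at means of 9.11 and 6.54, and the points rise together with r = 0.866 after group means are removed.

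The arrays also differed in markers of other tissues, sex and time of day. Ucp1, the marker of brown fat, was 9.31 in knockout normoxia 2 and 7.66 in control hypoxia 1, against at most 4.28 in the 10 others (log2). Nppa, a hormone of heart atria, was 11.94 in knockout normoxia 2 and 9.41 in knockout normoxia 4. Y-linked genes were high in 4 of 6 normoxic and 2 of 6 hypoxic arrays, so sex was not balanced over oxygen. The clock genes Dbp minus Arntl, which peak at opposite times of day, separated all 6 hypoxic arrays (5.64 or above) from all 6 normoxic ones (3.72 or below). Markers of developing thymocytes stayed low in all 12 arrays, with Rag1 from 3.29 to 3.62 and Dntt from 2.90 to 3.11. These markers were picked from the fixed lists after their values were seen, except Nppa, Dbp and Arntl.

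In control lungs, chronic hypoxia raised 27 of 34 extracellular matrix genes, 8 of 15 cholesterol synthesis genes and some genes of smooth muscle and glycolysis, and lowered some markers of aerocyte capillaries, ciliated cells, B cells and NK cells. These lists passed at the preset correlation, and 0 lists did with an estimated correlation (smallest adjusted p = 0.21). Ntrk2, the receptor for brain-derived neurotrophic factor, rose most, from 4.49 to 7.71 (log2), a 9.35-fold change (3.23 ± 0.19, adjusted p = 1.6e-05). Adam23, a cell adhesion protein of the ADAM family, rose by 2.29 ± 0.27, Cdk19, a kinase of the Mediator complex, by 1.89 ± 0.10, and Npy1r, a receptor of neuropeptide Y, by 1.59 ± 0.14. The matrix protein Tnc rose by 1.86 ± 0.34, the antibacterial lectin Reg3g by 1.96 ± 0.31 and the clock output gene Dbp by 1.64 ± 0.41. The translation factor Eef1a1 rose by 2.07 ± 0.32 from a low level of 3.67. The largest decreases were those of Phxr4 (-2.25 ± 0.44), the axonemal dynein Dnah12 (-2.21 ± 0.38), Neat1 (-1.80 ± 0.27), the natriuretic peptide clearance receptor Npr3 (-1.75 ± 0.27) and the core clock gene Arntl (-1.75 ± 0.33). The splicing factor Luc7l3 fell by 1.71, and the cilium genes Ccdc39 and Cfap47 fell by 1.71 and 1.69 on the log2 scale.

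In numbers, 2839 of 24704 genes changed with hypoxia in control lungs (11.5%), 1323 higher and 1516 lower, and 330 of them changed at least 2-fold, 97 up and 233 down. Of the 2839 genes, 2813 had no overlap between the 3 hypoxic and 3 normoxic arrays, which 27.7% of all genes showed and chance gives in 10%. The count was 1084 without control normoxia 1, 978 without control normoxia 2 and 808 without control hypoxia 2. It was 2 with the mean of the nuclear RNAs as a covariate, 7 with the clock covariate, 1794 with the Y-linked covariate and 1100 in a fit of the 6 control arrays alone. The median fold ratio of the 2839 genes, with over without the covariate, was 0.425 for nuclear RNA, 0.959 for the clock and 0.999 for the Y-linked genes. With the nuclear covariate Ntrk2 (3.32) and Cdk19 (1.79) kept their calls. Adam23 (2.5), Reg3g (2.81), Tnc (1.9), Npy1r (1.56) and Arntl (-2.28) stayed about as large or grew, but no longer passed. Eef1a1 moved to 0.80, Dbp to 1.19, Npr3 to -1.22, Phxr4 to -0.16, Luc7l3 to -0.10, Dnah12 to -0.41, Cfap47 to -0.19 and Ccdc39 to 0.24. Neat1 moved to -0.40, which says nothing, because Neat1 is part of the covariate. The animals had been selected by the authors partly on their response to hypoxia.

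Most matrix genes and some genes of the vessel wall rose. Of 34 collagen and extracellular matrix genes, 27 rose and 0 fell over all genes, and 30 rose adjusted over the list alone (list adjusted p = 2.1e-17; adjusted p = 0.26 with an estimated correlation). Examples are Mmp2, a gelatinase, by 1.54 ± 0.18, the elastic fibre protein Fbln2 by 1.08 ± 0.11, the basement membrane collagen Col4a1 by 1.03 ± 0.15 and the fibrillar collagen Col1a2 by 0.84 ± 0.13. Of 17 smooth muscle contractile genes, 6 rose and 0 fell, and 8 rose adjusted over the list alone (list adjusted p = 0.00020; adjusted p = 0.35 with an estimated correlation). Lmod1, an actin nucleator, rose by 0.94, the intermediate filament gene Des by 0.71, Myl9 by 0.70 and Tagln by 0.55, and the list mean went from 0.30 to 0.47 with the nuclear covariate. Fibroblast genes rose in 5 of 15, or 7 with 1 fall adjusted over the list alone (list adjusted p = 0.010; 0.33 as adjusted p with an estimated correlation), with Gdf10 at 1.35 and Mfap5 at 1.03. Pericyte genes rose in 4 of 10, or 5 adjusted over the list alone (list adjusted p = 0.033; 0.55 as adjusted p with an estimated correlation), among them Lamc3 (0.95) and Cspg4 (0.89).

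The BMP and TGF-beta response list had 6 rises and 2 falls among 24 genes, or 10 and 5 adjusted over the list alone, and did not pass (list adjusted p = 0.19). Bmp2 rose by 0.93 and Ccn2 by 0.78, whereas Bmp6 fell by 1.02 and the inhibitory Smad6 fell by 0.89. The pulmonary hypertension list did not pass either (list adjusted p = 0.53), with 3 rises and 4 falls among 35 genes, or 6 and 5 adjusted over the list alone. The chemokine Cxcl12 rose by 1.23, while the endothelin receptor Ednrb fell by 0.88, the endothelial TGF-beta coreceptor Eng fell by 0.61 and the hypoxia-inducible factor Epas1 fell by 0.47. Bmpr2, the BMP receptor mutated in familial pulmonary hypertension, fell by 1.03 (adjusted p = 0.013) and was -0.09 with the nuclear covariate. Edn1, which encodes endothelin, was 0.42 ± 0.15 (adjusted p = 0.089) and Pdgfb, a smooth muscle mitogen, 0.39 ± 0.15 (adjusted p = 0.11), so neither passed.

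Among metabolic genes, 6 of 21 HIF targets rose and 2 fell, or 8 and 2 adjusted over the list alone (list adjusted p = 0.0015; adjusted p = 0.21 with an estimated correlation). Ndrg1 rose by 0.97 ± 0.13, the prolyl hydroxylase subunit P4ha2 by 0.72, Mxi1 by 0.56 and lactate dehydrogenase Ldha by 0.47, whereas Vegfa fell by 0.37 (adjusted p = 0.025). The HIF list mean was 0.33, and 0.18 with the nuclear covariate. The glucose transporter Slc2a1 was 0.22 ± 0.11 (adjusted p = 0.23). Glycolysis genes rose in 4 of 13, or 5 adjusted over the list alone, led by Pfkl at 1.14 (list adjusted p = 0.0011; adjusted p = 0.33 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 15, or 10 adjusted over the list alone (list adjusted p = 3.5e-05; adjusted p = 0.35 with an estimated correlation). They included Cyp51 (1.12), Lss (1.01), Mvk (0.81) and Dhcr7 (0.67), enzymes at successive stages of the pathway, and the list mean went from 0.47 to 0.31 with the nuclear covariate. Fatty acid synthesis genes rose in 2 of 13, Srebf1 by 0.52 and Plin2 by 0.46, with the same number adjusted over the list alone (list adjusted p = 0.0069; adjusted p = 0.55 with an estimated correlation). Adipose genes were all 15 above 0, with 2 passing, or 3 adjusted over the list alone (list adjusted p = 0.0024; 0.60 as adjusted p with an estimated correlation). The lipid droplet gene Cidec rose by 1.35 and the lipase Pnpla2 by 0.47, and 1 of the 3 hypoxic arrays had the high Ucp1 given above. Without that array, control hypoxia 1, the adipose mean went from 0.81 to 0.34 (adjusted p = 0.12) and the fatty acid synthesis mean from 0.42 to 0.25 (adjusted p = 0.076), so both calls were lost. The 2 means were 2.40 and 1.16 with the nuclear covariate.

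Respiratory chain lists also passed, with small medians. Complex I genes had a median log2 change of 0.17, with 3 rises and 1 fall among 34, or 6 and 1 adjusted over the list alone (list adjusted p = 0.035; adjusted p = 0.59 with an estimated correlation). Complexes II to V had a median of 0.13 and 5 rises among 32, or 8 adjusted over the list alone, with Cox6b1 at 0.58 (list adjusted p = 0.010; adjusted p = 0.59 with an estimated correlation). The mitochondrial ribosome had a median of 0.18, with 3 rises and 1 fall among 38 both over all genes and adjusted over the list alone (list adjusted p = 0.044; adjusted p = 0.55 with an estimated correlation). With the nuclear covariate its mean was -0.05. NRF2 antioxidant genes rose in 3 of 21, or 4 adjusted over the list alone, with Osgin1 at 0.79 (list adjusted p = 0.023; adjusted p = 0.55 with an estimated correlation). With the nuclear covariate the NRF2 mean went from 0.23 to 0.061 and its call was lost (adjusted p = 0.83). The fatty acid oxidation (adjusted p = 0.061) and TCA cycle lists (adjusted p = 0.17) did not pass. The 14 NFAT5 and osmotic response targets did not pass (median 0.06, list adjusted p = 0.93). Of these, Slc6a6, a taurine transporter, rose by 0.79 ± 0.12 and the water channel Aqp5 by 0.30, or 2 rises and 1 fall adjusted over the list alone.

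Endothelial genes moved in both directions. Markers of aerocytes, the thin capillary cells of gas exchange, fell in 4 of 10, the same 4 adjusted over the list alone (list adjusted p = 0.0024; adjusted p = 0.35 with an estimated correlation). These were Fibin (-0.92), Ednrb (-0.88), Cyp4b1 (-0.63) and the VEGF receptor Kdr (-0.39). General capillary markers had 1 rise and 3 falls among 12, or 1 and 6 adjusted over the list alone, and did not pass (list adjusted p = 0.073). Plvap, which forms the diaphragms of capillary pores, fell by 1.16, Hilpda fell by 0.74 and Tmem100 fell by 0.44. Of 7 lymphatic markers 5 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.0060; adjusted p = 0.33 with an estimated correlation). Reln rose by 1.53, Mmrn1 by 0.92 and Flt4 by 0.56, whereas the hyaluronan receptor Lyve1 fell by 1.40. The lymphatic call was lost with the nuclear covariate (adjusted p = 0.073). Pan-endothelial markers did not pass (20 genes, median -0.01, list adjusted p = 0.77), with 3 rises such as Mmrn2 (0.78) and Emcn (0.60) and 2 falls such as Tek (-0.48), or 3 and 2 adjusted over the list alone. The angiogenic and VEGF list had 7 rises and 6 falls among 19, or 7 and 7 adjusted over the list alone (list adjusted p = 0.87), with Vegfc at 0.92 and Vegfd at 0.61. Notch genes had 2 rises and 3 falls among 14, or 4 and 5 adjusted over the list alone (list adjusted p = 0.77), with Heyl at 0.88, Hey2 at 0.80 and the tip cell ligand Dll4 at -0.88. Arterial markers (list adjusted p = 0.77) included Efnb2, which fell by 0.88, and venous markers had 0 calls among 8 (adjusted p = 0.72).

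Some markers of B and NK cells fell, and some of alveolar macrophages rose. Of 12 B cell markers 5 fell, also adjusted over the list alone, and all 12 lay below 0 (list adjusted p = 0.00020; adjusted p = 0.48 with an estimated correlation). Bank1 fell by 1.16, Blk fell by 0.72, Pax5 fell by 0.71 and Cr2 fell by 0.56, and the list mean went from -0.52 to -0.98 with the nuclear covariate. NK markers fell in 3 of 14, or 4 adjusted over the list alone, with Klrd1 at -1.29 (list adjusted p = 0.025; adjusted p = 0.55 with an estimated correlation). Alveolar macrophage markers rose in 6 of 13, or 8 adjusted over the list alone, including Trem2 (1.29) and the protease Ctsk (1.01) (list adjusted p = 0.00012; 0.33 as adjusted p with an estimated correlation). This list shares Cidec, Fabp4 and Lpl with the adipose list, and the rise of Cidec counts in both. The type 2 immunity list had 3 rises and 1 fall among 17, or 5 and 1 adjusted over the list alone, with the alarmin Il33 at 0.71 and Chil3 at 0.68 (list adjusted p = 0.025; adjusted p = 0.48 with an estimated correlation). This call was lost with the nuclear covariate (adjusted p = 0.072). MHC class II genes had 1 rise among 9, H2-DMb1 at 0.87, or 3 adjusted over the list alone (list adjusted p = 0.045; adjusted p = 0.65 with an estimated correlation), and their mean turned to -0.18 with the nuclear covariate. Inflammatory cytokines did not pass (list adjusted p = 0.71), with Il1b at -1.02 and the prostaglandin synthase Ptgs2 at -0.65 among their 2 rises and 2 falls. Monocyte markers did not pass (list adjusted p = 0.77) and went both ways, with Adgre4 at -1.26, Ccr2 at -0.95 and the complement genes C1qc at 1.01 and C1qb at 0.69.

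Ciliated cell markers fell in 5 of 17, or 8 adjusted over the list alone, with Spag17 at -1.10 (list adjusted p = 0.00028; adjusted p = 0.53 with an estimated correlation). Proliferation genes rose in 3 of 36, or 7 with 1 fall adjusted over the list alone, led by Plk1 (0.67) and Mcm2 (0.62) (list adjusted p = 0.0028; 0.55 as adjusted p with an estimated correlation). Immediate early genes fell in 4 of 22, or 5 adjusted over the list alone, with Fos at -1.01 and Egr1 at -0.65 (list adjusted p = 0.047; 0.74 as adjusted p with an estimated correlation). Their mean went from -0.21 to -0.48 with the nuclear covariate. Clock genes had 6 rises and 2 falls among 18, or 10 and 2 adjusted over the list alone (list adjusted p = 0.0027; adjusted p = 0.35 with an estimated correlation). Usp2 rose by 0.78 and Ciart by 0.68, whereas Clock fell by 1.20. Whether the lungs of both oxygen states were taken at the same hour is not given in the sources used here. Alveolar type 1 (adjusted p = 0.88) and type 2 markers (adjusted p = 0.31) did not pass as lists, although Igfbp2 rose by 1.48 ± 0.11, Napsa by 0.50 and Sftpd by 0.49, and Rtkn2 fell by 0.60.

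The remaining lists did not pass here, with small median log2 changes. Pathway medians were 0.15 for glucocorticoid response (adjusted p = 0.11), 0.16 for the unfolded protein response (adjusted p = 0.16), 0.11 for heat shock (adjusted p = 0.38), 0.11 for the cytosolic ribosome (adjusted p = 0.54) and 0.05 for interferon response (adjusted p = 0.96). Cell type medians were -0.10 for T cells (adjusted p = 0.13), -0.17 for platelets (adjusted p = 0.41), 0.03 for dendritic cells (adjusted p = 0.53), -0.09 for neutrophils (adjusted p = 0.77) and -0.01 for mast cells (adjusted p = 0.93). Plasma cell genes had 1 rise among 13 (adjusted p = 0.67), mesothelial genes 1 rise and 2 falls among 8 (adjusted p = 0.77), and club cell genes 1 fall among 11 (adjusted p = 0.31). Tissues that could adhere to a lung had medians of 0.12 for skeletal muscle (adjusted p = 0.31), 0.14 for cartilage (adjusted p = 0.088), -0.03 for thymus (adjusted p = 0.53), 0.06 for nerve and ganglion (adjusted p = 0.17), -0.07 for cardiac muscle (adjusted p = 0.87) and -0.01 for squamous epithelium (adjusted p = 0.90). Erythroid genes had a median of 0.10 (adjusted p = 0.33). Among members of these lists, the small heat shock protein Hspb1 rose by 0.94, the ribosomal gene Rps14 by 1.24, the dendritic cell gene Fscn1 by 1.11 and the growth cone gene Gap43 by 1.56. In the lists of interferon response, Notch, angiogenesis, arterial, alveolar type 1, neutrophil, dendritic, plasma, mast and squamous genes and NFAT5 targets, the median, mean and test did not all have the same sign. Across all 59 lists, 24 were called, 19 upward and 5 downward, 0 held with an estimated correlation and 15 passed with fry. Without control hypoxia 1 the complex I, immediate early, NRF2, fibroblast and NK calls were lost as well (adjusted p from 0.056 to 0.23), and the MHC class II mean went from 0.27 to 0.42.

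In knockout lungs, hypoxia raised 10 and lowered 2 of 18 clock genes, changed some glucocorticoid response, B cell and capillary genes, and raised 4 matrix genes. These lists passed at the preset correlation, and 0 lists did with an estimated correlation (smallest adjusted p = 0.10). Ntrk2 again rose most, by 2.98 ± 0.19 (adjusted p = 3.9e-05), followed by the clock genes Dbp (2.41 ± 0.41) and Per2 (2.06 ± 0.34), the stress-responsive actin regulator Fam107a (2.02 ± 0.22), Adam23 (2.01 ± 0.27), the anion transporter family member Slc26a10 (1.73 ± 0.21), Cdk19 (1.71 ± 0.10) and Npy1r (1.66 ± 0.14). The clock activators Arntl (-2.75 ± 0.33) and Npas2 (-1.92 ± 0.39) fell most. The cytokine Il1b fell by 1.51, the B cell gene Ms4a1 fell by 1.49, Fam124b fell by 1.48, the interferon-inducible Ifi209 fell by 1.42, Plvap fell by 1.35 and Igfbp3, a binding protein of insulin-like growth factors, fell by 1.30 on the log2 scale. In all, 282 genes changed (1.14%), 158 higher and 124 lower, and all 282 had no overlap between the 3 hypoxic and 3 normoxic arrays. The count was 139 without knockout normoxia 1, 71 without knockout normoxia 2, 130 without knockout normoxia 4, 137 without knockout hypoxia 2, 148 without knockout hypoxia 3 and 80 without knockout hypoxia 4. It was 162, 0 and 166 with the nuclear, clock and Y-linked covariates, 40 with the replicate block and 508 with array weights. The median fold ratio of the 282 genes was 0.950 with the nuclear, 0.959 with the clock and 0.997 with the Y-linked covariate, over without it.

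Clock genes had 10 rises and 2 falls among 18, or 14 and 4 adjusted over the list alone (list adjusted p = 3.5e-09; adjusted p = 0.10 with an estimated correlation), including Ciart at 1.32 and Bhlhe40 at 1.02. Glucocorticoid response genes rose in 5 of 15, or 9 with 1 fall adjusted over the list alone (list adjusted p = 4.9e-07; adjusted p = 0.10 with an estimated correlation). Per1, shared with the clock list, rose by 1.21, and the metallothioneins Mt2 and Mt1 rose by 1.05 and 0.59. B cell markers fell in 5 of 12, or 11 adjusted over the list alone (list adjusted p = 6.2e-15; adjusted p = 0.10 with an estimated correlation), with Bank1 at -1.17 and Pax5 at -1.16. T cell markers had 1 fall among 14, Trbc1 at -0.68, or 5 adjusted over the list alone (list adjusted p = 0.00021; adjusted p = 0.32 with an estimated correlation). Aerocyte markers fell in 3 of 10, or 5 adjusted over the list alone, with Ednrb at -0.77 and Kdr at -0.60 (list adjusted p = 1.0e-06; 0.10 as adjusted p with an estimated correlation). General capillary markers had 1 rise, Cxcl12 at 0.89, and 2 falls among 12, or 1 and 7 adjusted over the list alone (list adjusted p = 8.7e-05; adjusted p = 0.14 with an estimated correlation). Lymphatic markers had 2 rises and 1 fall among 7, or 5 and 1 adjusted over the list alone (list adjusted p = 0.00040; adjusted p = 0.10 with an estimated correlation), with Reln at 1.34, Mmrn1 at 0.98 and Lyve1 at -0.85.

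Matrix genes rose in 4 of 34 in knockout lungs, or 14 with 1 fall adjusted over the list alone (list adjusted p = 6.9e-08; adjusted p = 0.32 with an estimated correlation). These were Ltbp2 (1.04), Mmp2 (0.92), fibronectin Fn1 (0.66) and Fbln5 (0.43). Smooth muscle contractile genes had 0 calls over all genes among 17, with 1 rise adjusted over the list alone, a median of -0.07 and Myl9 at 0.52 ± 0.14 (adjusted p = 0.11; list adjusted p = 0.84). HIF targets rose in 2 of 21, Ndrg1 by 0.86 and Pfkfb3 by 0.76, or 3 adjusted over the list alone (list adjusted p = 0.021; adjusted p = 0.14 with an estimated correlation). The NFAT5 and osmotic response targets did not pass (list adjusted p = 0.16), with 1 rise, Slc6a6 at 0.78, or 3 rises and 1 fall adjusted over the list alone. The cholesterol list passed with 0 of 15 members passing on either count (median 0.18, adjusted p = 0.00048; 0.39 as adjusted p with an estimated correlation). Alveolar macrophage markers rose in 3 of 13, or 7 adjusted over the list alone, with Ctsk at 0.96 (list adjusted p = 0.00079; adjusted p = 0.33 with an estimated correlation). Neutrophil markers had 1 rise and 2 falls among 15, or 1 and 6 adjusted over the list alone, with S100a9 at -0.60 and S100a8 at -0.53 (list adjusted p = 0.00069; adjusted p = 0.10 with an estimated correlation). Among the pulmonary hypertension genes, whose list did not pass (list adjusted p = 0.84), the endothelial nitric oxide synthase Nos3 rose by 0.64 and Epas1 fell by 0.66. Bmpr2 (-0.71 ± 0.21, adjusted p = 0.15), Vegfa (-0.28 ± 0.09, adjusted p = 0.20), Edn1 (-0.28 ± 0.15, adjusted p = 0.49) and Pdgfb (-0.14 ± 0.15, adjusted p = 0.81) did not pass.

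Lists of heart and fat also passed downward in knockout lungs, where the normoxic group held the arrays with high Nppa and Ucp1. Cardiac muscle genes had 0 calls over all genes among 19 and 14 falls adjusted over the list alone (median -0.88, adjusted p = 3.4e-09; 0.39 as adjusted p with an estimated correlation), with Nppa at -2.83 ± 0.70 (adjusted p = 0.090). Adipose genes had a median of -0.48 (list adjusted p = 0.0052; adjusted p = 0.63 with an estimated correlation), fatty acid oxidation -0.20 (list adjusted p = 0.0038; adjusted p = 0.55 with an estimated correlation) and the TCA cycle -0.15 (list adjusted p = 0.0017; adjusted p = 0.55 with an estimated correlation), each with 0 calls on either count. Without knockout normoxia 2 the mean went from -0.77 to -0.19 for adipose, from -0.24 to -0.040 for fatty acid oxidation and from -0.21 to -0.039 for the TCA cycle, and these calls were lost (adjusted p from 0.66 to 0.77), as was that of pericytes (adjusted p = 0.11). The cardiac mean went from -1.04 to -0.63. Without the 2 arrays of highest Ucp1, a choice made after seeing the data, 51 genes were called, of which 49 were among the 282. The other lists called were immediate early genes (median -0.20, Egr1 at -1.14), NK cells (-0.25), platelets (-0.35), ciliated cells (-0.22), MHC class II (0.32), proliferation (0.11), type 2 immunity (0.22, Ccl17 at 1.28) and pericytes (0.13). Over all genes they held 1 fall of an immediate early gene and 3 rises of type 2 genes. Adjusted over the list alone there were 7 falls of immediate early genes, 1 each of NK and platelet genes, 5 rises of MHC class II genes, 4 of pericyte genes, and 5 rises and 1 fall of type 2 genes. Their adjusted p-values lay between 0.00016 and 0.043, and between 0.32 and 0.55 as adjusted p with an estimated correlation. With the nuclear covariate the calls of HIF targets (adjusted p = 0.054), TCA cycle (adjusted p = 0.059) and adipose genes (adjusted p = 0.21) were lost, with means of 0.12, -0.11 and -0.34 in place of 0.16, -0.21 and -0.77. Of the 59 lists, 24 were called, 11 upward and 13 downward, 0 held with an estimated correlation and 8 passed with fry.

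**Figure D2:**
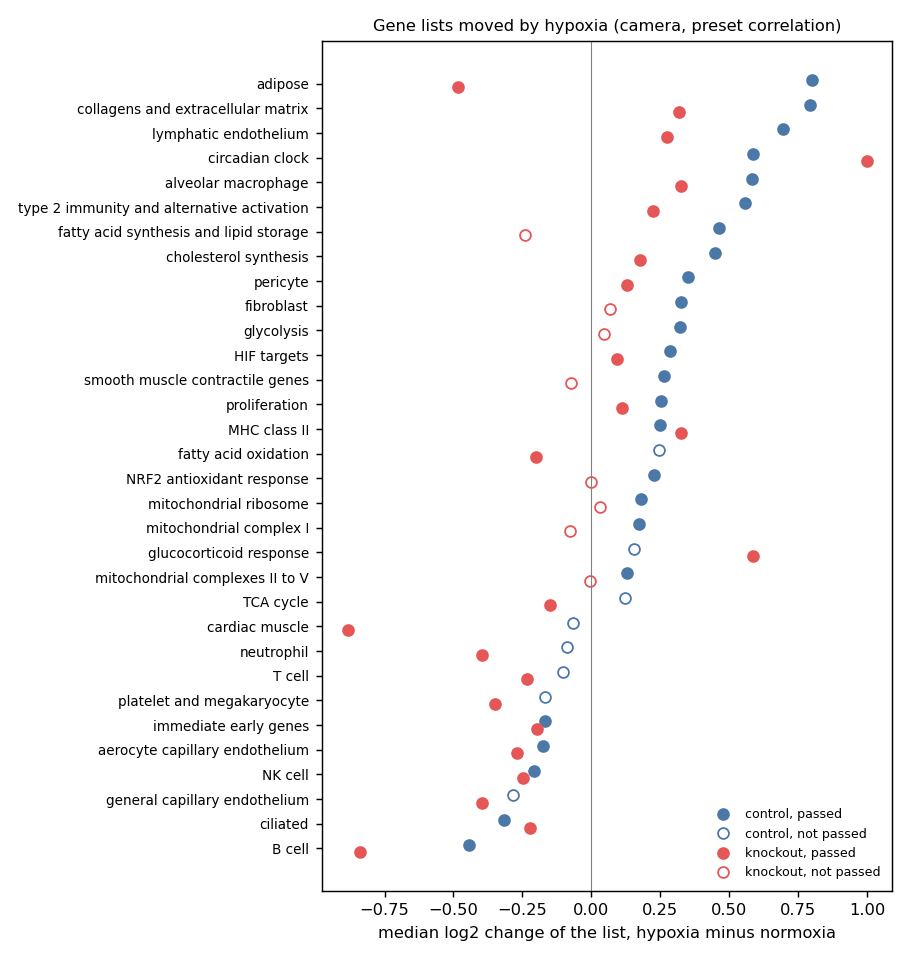
Median log2 change with hypoxia of each gene list called in either genotype, with control lungs in blue and knockout lungs in red, and filled points for lists that passed at the preset correlation. Matrix genes have medians of 0.79 in control and 0.32 in knockout lungs, B cell genes -0.44 and -0.84, and clock genes 0.58 and 1.00.

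The hypoxia responses of the 2 genotypes, which share no arrays, overlapped strongly and in the same direction. Of the genes called higher in knockout lungs, 115 of 158 were also called higher in control lungs (8.46 expected for independent lists, Fisher's exact two-sided p = 6.3e-111). Of those called lower, 94 of 124 were shared (7.61 expected, Fisher's exact two-sided p = 6.5e-88), and 0 genes were called in opposite directions. Genes are not independent of each other, so these p-values are too small. Across all genes the log2 changes correlated with r = 0.549 and rho = 0.50. Among the 2839 genes called in control lungs, 2607 (91.8%) had the same sign in knockout lungs, with a median knockout-to-control ratio of 0.426. Among the 282 called in knockout lungs, 278 (98.6%) had the same sign in control lungs, with a median ratio of 0.843. Both ratios are of genes picked for being large in the denominator, which by itself brings a ratio below 1.

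**Figure D3:**
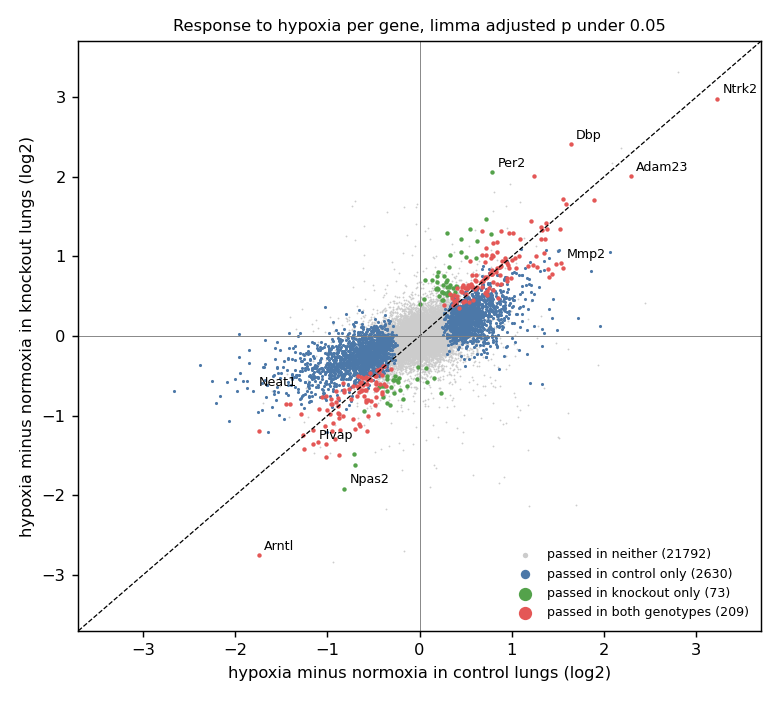
Log2 change with hypoxia in control lungs (horizontal) against knockout lungs (vertical), 1 point per gene, coloured by where the gene was called, with a dashed line of equal change. The 209 genes called in both genotypes lie along one direction, with Ntrk2 at 3.23 and 2.98 and Arntl at -1.75 and -2.75.

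Over both genotypes together, 3622 genes changed with hypoxia, 1795 higher and 1827 lower, and 137 of them at least 2-fold, 57 up and 80 down. Ntrk2 rose by 3.10 ± 0.13, Adam23 by 2.15, Dbp by 2.02, Cdk19 by 1.80 and Slc26a10 by 1.64. An immunoglobulin light chain segment of the Igkv14 family rose by 3.06 (adjusted p = 0.013), and the heavy chain segments Ighv11-2 (2.27 ± 0.49) and Ighv11-1 (2.13 ± 0.44) rose as well. Arntl fell by 2.25, Nppa fell by 1.89, Dnah12 fell by 1.52, the sulfotransferase Sult1d1 fell by 1.42, Phxr4 fell by 1.41, Npas2 fell by 1.37, Npr3 fell by 1.35 and Ifi209 fell by 1.34. The fall of Nppa rests in part on knockout normoxia 2 (11.94) and knockout normoxia 4 (9.41), while every other array lay at 8.44 or below. Matrix genes rose in 26 of 34, or 29 with 1 fall adjusted over the list alone (list adjusted p = 8.3e-15; adjusted p = 0.22 with an estimated correlation). B cell markers fell in 8 of 12, or 12 adjusted over the list alone (list adjusted p = 3.2e-09; adjusted p = 0.24 with an estimated correlation). Clock genes had 14 rises and 3 falls among 18 on either count (list adjusted p = 1.1e-05; adjusted p = 0.22 with an estimated correlation). Glucocorticoid response genes had 7 rises and 1 fall among 15 on either count, Fkbp5 among them at 1.09 (list adjusted p = 0.00081; adjusted p = 0.25 with an estimated correlation). Immediate early genes fell in 9 of 22 on either count, with Egr1 at -0.89 (list adjusted p = 0.0024; adjusted p = 0.55 with an estimated correlation). Bmpr2 fell by 0.87 (adjusted p = 0.0038) and Vegfa fell by 0.33 (adjusted p = 0.0077). The count was 2254 without knockout normoxia 2, 2282 without control hypoxia 2, 2283 without knockout hypoxia 2 and 2346 without knockout hypoxia 4. It was 60 with the nuclear covariate, 0 with the clock covariate and 2180 with the Y-linked covariate, and 22 of the 59 lists were called, 13 upward and 9 downward, 0 of them with an estimated correlation, while 26 lists passed with fry. The median fold ratio of the 3622 genes was 0.536 with the nuclear, 0.913 with the clock and 1.00 with the Y-linked covariate, over without it.

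**Figure D4:**
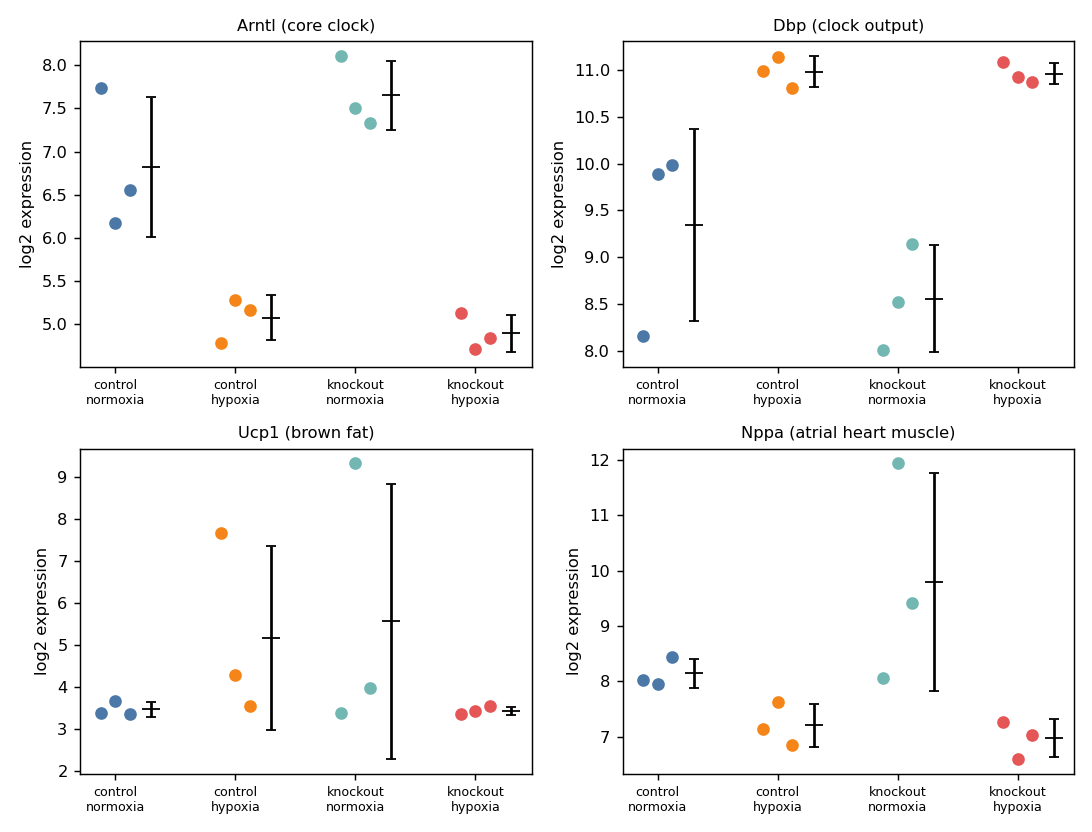
Levels (log2) of the clock genes Arntl and Dbp, the brown fat gene Ucp1 and the atrial gene Nppa in the 4 groups, 1 point per array with the group mean and SD beside it. Dbp minus Arntl is 5.64 or more in all 6 hypoxic arrays and 3.72 or less in all 6 normoxic ones, and Ucp1 reaches 9.31 in 1 knockout normoxic array and 7.66 in 1 control hypoxic array.

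Knockout and control lungs in normoxia differed in a single gene, the predicted gene Gm10566, named here after its value was seen. It was 0.90 ± 0.09 higher in knockout lungs (adjusted p = 0.012), and it was not called in the fit of these 6 arrays alone. The next strongest differences did not pass. Cox6b1, a subunit of cytochrome oxidase, was 0.65 ± 0.10 higher (adjusted p = 0.26), the complex III assembly factor Uqcc2 0.57 (adjusted p = 0.32), the chitinase Chia1 0.64 (adjusted p = 0.32), the immunoglobulin gene Ighg2b 2.21 ± 0.40 (adjusted p = 0.38) and Dpy19l3 0.46 (adjusted p = 0.38). Lower values were Fthl17b at -1.0 (adjusted p = 0.26), Ppid at -0.68, the DNA damage gene Ddb2 at -0.49 and Zdhhc16 at -0.41 (adjusted p = 0.38 each), and Gnrh1 at -0.61 (adjusted p = 0.44). Edn1 was 0.56 ± 0.15 (adjusted p = 0.56). Ighg2b lay between 4.46 and 5.85 in the 6 control arrays and between 6.58 and 7.79 in the 6 knockout arrays of both oxygen states. At an unadjusted p under 0.05, limma gave 1793 genes, where 1235.2 are expected without any effect. Without any one of the 6 arrays of this comparison 0 genes were called, as with the replicate block.

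By list, 19 of 59 were called for knockout in normoxia, 17 upward and 2 downward, and mitochondrial, lipid and matrix genes lay higher in knockout lungs. Other splits of the same 6 arrays called a median of 16 lists and up to 26, so the number of calls does not set the genotypes apart. Of the 19 calls, 7 were lost without knockout normoxia 2, 5 without control normoxia 2 and 4 without knockout normoxia 1. Complex I genes lay above 0 in 29 of 34 (median 0.22, adjusted p = 3.0e-08; 0.32 as adjusted p with an estimated correlation), with Ndufv3 at 0.61. Complexes II to V did so in 29 of 32 (median 0.16, adjusted p = 3.0e-08; 0.32 as adjusted p with an estimated correlation). Matrix genes lay above 0 in 33 of 34 (median 0.24, adjusted p = 3.0e-08; 0.32 as adjusted p with an estimated correlation), with Fbln2 at 0.41. Fatty acid synthesis had a median of 0.52 (adjusted p = 1.8e-07), with the lipogenic gene Thrsp at 2.27 and fatty acid synthase Fasn at 0.63, cholesterol synthesis of 0.30 (adjusted p = 1.9e-06) and smooth muscle of 0.26 (adjusted p = 2.7e-05), each with 0.32 as adjusted p with an estimated correlation. Adipose genes had a median of 0.74, cardiac genes 0.63, fatty acid oxidation 0.31 and the TCA cycle 0.23, with adjusted p from 2.5e-07 to 2.9e-06, and from 0.43 to 0.51 with an estimated correlation. Without knockout normoxia 2, the array with the highest Ucp1 and Nppa, the mean went from 0.85 to 0.28 for adipose, from 0.60 to 0.18 for cardiac muscle, from 0.27 to 0.063 for fatty acid oxidation and from 0.24 to 0.066 for the TCA cycle, and these 4 calls were lost (adjusted p from 0.069 to 0.11), as were those of glycolysis, glucocorticoid response and fibroblasts. It went from 0.64 to 0.32 for fatty acid synthesis, from 0.19 to 0.12 for complexes II to V and from 0.21 to 0.12 for smooth muscle, which stayed called. Clock genes were lower (median -0.35, adjusted p = 0.0060; 0.39 as adjusted p with an estimated correlation), with Per2 at -0.99, as were glucocorticoid response genes (median -0.22, adjusted p = 0.039; 0.43 as adjusted p with an estimated correlation). In Dbp minus Arntl, control normoxia 1 (0.42) lay among the knockouts (-0.10 to 1.81), unlike control normoxia 2 (3.72) and 4 (3.42). Time of day thus cannot be excluded. Alveolar macrophages (0.18), mitochondrial ribosome (0.08), glycolysis (0.16), unfolded protein response (0.10), plasma cells (0.06), fibroblasts (0.08) and proliferation (0.07) were the others, with adjusted p up to 0.041 and from 0.32 to 0.73 with an estimated correlation. Members passed in none of the 19 lists over all genes. Adjusted over the list alone, 4 complex I genes, 6 of complexes II to V, 4 each of fatty acid and cholesterol synthesis, 2 of the TCA cycle and 1 of glycolysis were higher and 1 clock gene was lower. With fry 0 lists passed, and 12 were called without knockout normoxia 2. With the nuclear covariate the calls of mitochondrial ribosome, plasma cell, glucocorticoid response, glycolysis, unfolded protein response and fibroblast genes were lost (adjusted p from 0.061 to 0.98). The mean was 0.026 in place of 0.11 for the mitochondrial ribosome, 0.17 in place of 0.44 for plasma cells and -0.063 in place of -0.17 for glucocorticoid response. It was 0.13 in place of 0.18 for glycolysis, 0.073 in place of 0.098 for the unfolded protein response and 0.14 in place of 0.15 for fibroblasts. Other means grew with the covariate, from 0.60 to 1.09 for cardiac muscle, from 0.85 to 1.5 for adipose, from 0.24 to 0.40 for the TCA cycle and from 0.27 to 0.42 for fatty acid oxidation.

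In hypoxia, 0 genes differed between knockout and control lungs with limma (smallest adjusted p = 0.38), with 1259 at an unadjusted p under 0.05 against 1235.2 expected. The fit of these 6 arrays alone called 1, as did the fit without knockout normoxia 4. The netrin receptor Unc5a was 1.13 ± 0.17 and Gdap10 0.93 ± 0.14 (adjusted p = 0.38 each), and Ighg2b (2.01 ± 0.40), Ighv6-3 (3.10 ± 0.62) and Ighv1-75 (1.37) had adjusted p = 0.95. Lower values were Camk2b at -0.72, Sec61g at -0.61, Plcd3 at -0.57, Ttc28 at -0.50 and the monoamine oxidase Maoa at -0.33, none of which passed. Pdgfb was -0.31 ± 0.15 and Edn1 -0.13 ± 0.15. Matrix genes lay below 0 in 31 of 34 (median -0.20, adjusted p = 6.1e-06; 0.72 as adjusted p with an estimated correlation), with Col18a1 at -0.33 and Thbs1 at -0.45. B cell genes lay below 0 in 12 of 12 (median -0.34, adjusted p = 1.2e-05; 0.72 as adjusted p with an estimated correlation). Pan-endothelial genes lay below 0 in 17 of 20 (median -0.10, adjusted p = 0.019; 0.77 as adjusted p with an estimated correlation), with the endothelial transcription factor Erg at -0.27. Other medians were -0.78 for adipose, -0.36 for cardiac muscle, -0.13 for smooth muscle, -0.19 for neutrophils, -0.14 for general capillaries, -0.18 for pericytes, -0.09 for cartilage, -0.10 for fatty acid oxidation, 0.12 for ciliated cells and 0.19 for plasma cells. Their adjusted p lay between 4.5e-05 and 0.038, and between 0.12 and 0.77 with an estimated correlation. The 13 called lists, 2 upward and 11 downward, held 0 called genes over all genes or adjusted over the list alone, and fry called 0. The calls of pan-endothelial (adjusted p = 0.43) and cartilage genes (adjusted p = 0.11) were lost with the nuclear covariate. There were 7 called lists without knockout hypoxia 2 and 8 without knockout hypoxia 3. Without control hypoxia 1, the array with Ucp1 at 7.66, the adipose mean went from -0.72 to -0.26 (adjusted p = 0.18) and that of fatty acid oxidation from -0.13 to -0.043 (adjusted p = 0.56), and both calls were lost, as was that of plasma cells (adjusted p = 0.31). The pan-endothelial mean went from -0.087 to -0.15 without this array and stayed called.

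Averaged over oxygen states, limma called 0 genes for knockout (smallest adjusted p = 0.22, 1053 at an unadjusted p under 0.05 against 1235.2 expected). Ighg2b came nearest at 2.11 ± 0.28, followed by Unc5a at 0.75 and Uqcc2 at 0.41 (adjusted p = 0.42 each), Ighv1-75 at 0.94 and the chemokine Ccl8 at 0.35 (adjusted p = 0.75 each). Lower values were Fthl17b at -0.54, Krtap5-1 at -0.51, Apol9a at -0.46, Ddb2 at -0.30 and Zdhhc16 at -0.29, which did not pass. In all, 16 lists were called, 12 upward and 4 downward, with medians between -0.19 and 0.20 and a smallest adjusted p of 0.64 with an estimated correlation. Complex I (0.13), complexes II to V (0.07), cholesterol synthesis (0.13) and plasma cell genes (0.10) had the smallest p among those higher, with Jchain at 0.96, and B cell (-0.19) and pan-endothelial genes (-0.06) among those lower. Adjusted over the list alone, 1 gene each of complexes II to V and cholesterol synthesis and 2 each of plasma cells, alveolar macrophages and type 2 immunity were higher. With fry 0 lists passed, and 10 were called without knockout normoxia 2. The call of dendritic cell genes was lost with the nuclear covariate (adjusted p = 0.10).

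The interaction asks directly whether hypoxia acts differently in the 2 genotypes. Gm10566 alone passed (-1.24 ± 0.13, adjusted p = 0.017), with a rise of 1.32 in control lungs and a change of 0.09 in knockout lungs. The count was 3 without control normoxia 4, and 0 without control normoxia 1 or 2, without any one control hypoxia or knockout normoxia array, and without knockout hypoxia 2. At an unadjusted p under 0.05 there were 2037 genes against 1235.2 expected. Of the 2839 genes called in control lungs, 963 (33.9%) were among such genes and 2 passed when adjusted over these 2839 alone. The control contrast enters the interaction with a minus sign, so genes picked for a large control change lean towards an interaction by construction. Neither number is therefore a test of a difference. The larger number of calls in control lungs, 2839 against 282, was not matched by genes shown to differ one by one. Small differences could be missed, as 0% of simulated interactions of 0.5 were recovered. Values that did not pass include Gdap10 at 1.45 ± 0.20 (adjusted p = 0.14), and Gnrh1 at 0.88, Arhgef38 at 0.86, Rab26os at 0.81, Tubd1 at 0.64, Rps3a2 at -0.94, Dpy19l3 at -0.66, Cox6b1 at -0.65, Tbc1d13 at -0.62 and Fbxo21 at -0.60 (adjusted p = 0.57 each). Edn1 was -0.70 ± 0.21 (adjusted p = 0.57) and Pdgfb -0.53 ± 0.21 (adjusted p = 0.59).

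By list, matrix genes rose less with hypoxia in knockout than in control lungs, and smooth muscle genes rose as a list in control lungs only. Of 100 splits of the genotypes within oxygen states, 37 gave as many called lists, so chance cannot be excluded. Both oxygen states enter these differences. Matrix genes lay 0.24 higher in knockout lungs in normoxia and 0.19 lower in hypoxia (means). Smooth muscle genes lay 0.21 higher and 0.17 lower, and the 0.21 was 0.12 without knockout normoxia 2. All 34 matrix genes had interactions below 0 (median -0.41, adjusted p = 2.0e-11; 0.41 as adjusted p with an estimated correlation), with Col3a1 at -0.84 and Thbs1 at -0.74. Smooth muscle genes had 16 of 17 below 0 (median -0.36, adjusted p = 2.3e-07; 0.41 as adjusted p with an estimated correlation), with Lmod1 at -0.69 and Myh11 at -0.40. Clock (0.35, adjusted p = 0.016) and glucocorticoid response genes (0.36, adjusted p = 0.0070) were the called lists with positive medians, with Per2 at 1.27 and Zbtb16 at 1.41, and 0.44 and 0.42 as adjusted p with an estimated correlation. Negative medians were also those of adipose (-1.31), cardiac muscle (-0.97), fatty acid synthesis (-0.62) and fatty acid oxidation genes (-0.39), with Adipoq at -1.93 and Myh6 at -2.01. These have adjusted p from 5.7e-09 to 1.0e-05, and from 0.42 to 0.50 with an estimated correlation, and both arrays with high Ucp1 enter them with a minus sign. Of the 16 lists called, 2 upward and 14 downward, 0 members passed over all genes. Adjusted over the list alone, 1 matrix, 6 smooth muscle, 2 TCA cycle, 1 complexes II to V and 2 glycolysis genes were lower and 1 clock gene was higher. With fry 0 lists passed. With the nuclear covariate the call was lost for glycolysis, cholesterol synthesis, glucocorticoid response, fibroblast, neutrophil and B cell genes (adjusted p from 0.055 to 0.98), and the B cell mean went from -0.34 to 0.0017. The fibroblast mean was then -0.21 in place of -0.23, and the neutrophil, adipose and cardiac means grew. The NFAT5 and osmotic response targets did not pass (median 0.11, adjusted p = 0.34).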

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

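The tests of nuclear RNA, of clock phase and of brown fat below were chosen only after the results were seen, and the counts over other splits of the samples were fixed before.

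Hypoxia responses that differed between the genotypes by a test of the difference itself were those of 16 gene lists and 1 gene. The list medians of the interaction (log2) were -0.41 for extracellular matrix, -0.36 for smooth muscle, -0.14 for fibroblasts, -0.17 for glycolysis, -0.19 for complex I, -0.19 for complexes II to V, -0.26 for the TCA cycle, -0.39 for fatty acid oxidation, -0.30 for cholesterol synthesis and -0.62 for fatty acid synthesis. They were -1.31 for adipose, -0.97 for cardiac muscle, -0.40 for B cells, -0.18 for neutrophils, 0.35 for clock genes and 0.36 for glucocorticoid response genes. The gene was Gm10566, at -1.24. None of the 16 list calls held with an estimated correlation. With the nuclear RNA covariate 6 of them were lost, and the B cell mean went from -0.34 to 0.0017. The neutrophil mean was -0.41 in place of -0.37. The means of adipose (-2.74 in place of -1.57), cardiac muscle (-1.80 in place of -0.97) and the TCA cycle (-0.56 in place of -0.29) grew. The matrix mean stayed at -0.43 and the smooth muscle mean was -0.50 in place of -0.37, and both lists stayed called at the preset correlation. Of 100 splits of the genotypes within oxygen states, 37 gave as many called lists (real 16, highest other 26) and 7 gave as many called genes (real 1, highest other 672), so chance can be excluded for neither count. The split with 672 genes parts arrays of high from arrays of low nuclear RNA mean, which points to a structure of the samples. It also puts both arrays with high Ucp1 on the side of high nuclear RNA, so nuclear RNA need not be that structure.

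Probe sets without a gene symbol lie outside the genes compared, and 94 of 723 changed with hypoxia in control lungs and 10 in knockout lungs.

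More genes were called for hypoxia in control lungs (2839) than in knockout lungs (282). Of 100 splits in which genotype was assigned at random within each oxygen state, 17 gave as large a difference between the counts (real 2557, highest other 5196), so chance cannot be excluded. A shift of nuclear-retained RNA between arrays could have produced the difference. With the nuclear RNA covariate the median fold ratio in control lungs, with over without it, was 0.425. Of the called genes, 2 stayed called in control and 148 in knockout lungs. These counts cannot decide the question, because the nuclear mean separates control normoxia (6.32 or above) from control hypoxia (5.94 or below) completely. Mmp2 went from 1.54 to 1.70 yet lost its call (adjusted p = 0.31), while Bmpr2 went from -1.03 to -0.09. Hypoxia itself may lower nuclear RNAs, in which case the covariate removes part of the response, and this was not tested. A weaker response in lungs without endothelial NFAT5 stays open as a biological explanation, untested apart from these.

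Clock genes were shifted in hypoxic lungs, and the lowest hypoxic array lay 1.92 above the highest normoxic one for Dbp minus Arntl (log2). Lungs taken at another time of day and an effect of hypoxia on the clock cannot be told apart here, because clock phase separates the oxygen states completely. For all genes called over both genotypes, clock genes included, the median fold ratio with over without the clock covariate was 0.913, but the SE grew by a median factor of 2.78, which keeps this open as well. An effect of hypoxia on the clock was not tested separately.

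Brown fat and heart tissue on some preparations could account for the interactions of the adipose and TCA cycle lists, because 2 arrays held high Ucp1, 1 in knockout normoxia and 1 in control hypoxia. Without them, the mean interaction kept 18.5% of its size for the TCA cycle, as this explanation needs, and 59.6% for cardiac muscle, which leaves that list open. It kept 34.0% for adipose genes, which decides nothing, because the arrays were picked on Ucp1, an adipose gene. It kept 26.3% for fatty acid oxidation, 42.5% for fatty acid synthesis, 51.3% for complex I, 63.9% for complexes II to V and 79.3% for fibroblasts. The calls of the TCA cycle, fatty acid oxidation, complex I and fibroblast lists were lost (adjusted p from 0.13 to 0.27). The 12 others stayed called, with adipose at adjusted p = 0.00035, cardiac muscle at 0.0016 and fatty acid synthesis at 0.016. It kept 101% for extracellular matrix, 87.8% for smooth muscle and 99.7% for glycolysis, which argues against the brown fat of these 2 arrays as the source of these 3. Other adhering tissue was not tested, since knockout normoxia 4, with the heart gene Nppa at 9.41, stayed in the fit. Cholesterol synthesis kept 102% of its mean but its median went from -0.30 to -0.16. Without the 2 arrays 13 of 15 adipose, 18 of 19 cardiac and 17 of 17 TCA cycle genes stayed above the low-signal filter, which does not show whether their RNA comes from lung, and an effect of endothelial NFAT5 on lipid metabolism stays open as untested.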

How the results depend on the processing

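Alternatives were planned in advance, except leaving out the 2 arrays with the highest Ucp1 and the clock, nuclear RNA, and Malat1 and Neat1 covariates. The number of arrays limits precision throughout, as does signal near background for genes of low level. Averaging the probe sets of a gene, a further quantile normalization and median centring moved nothing and so say nothing about stability.

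Counts stayed within 1.5 times with a robust trended prior (2805, 308, 3592, 1, 0, 0 and 1 genes for hypoxia in control lungs, in knockout lungs and averaged, knockout in normoxia, in hypoxia and averaged, and interaction) and with a filter on low signal (3090, 297, 3802, 1, 0, 0 and 1). With array weights hypoxia in knockout lungs gave 508 genes and the interaction 2. With an adjusted p under 0.10 the counts were 4672 and 520 in control and knockout lungs and 403 in both. In fits of only the arrays compared they were 1100 for hypoxia in control lungs, 0 for knockout in normoxia and 1 in hypoxia. With the Y-linked covariate they were 1794, 166 and 2180 for hypoxia in control lungs, in knockout lungs and averaged, and 0 for the interaction, with median fold ratios of 0.999, 0.997 and 1.00 for the genes called for hypoxia. The fits of only the arrays compared hold fewer arrays, and for the other settings the cause was not tested.

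With an estimated correlation 0 lists were called in any comparison. With fry 15 were called for hypoxia in control lungs, 8 in knockout lungs and 26 averaged, and 0 for knockout or the interaction.

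The replicate block gave 40 genes for hypoxia in knockout lungs, 0 for knockout in normoxia and 0 for the interaction, and kept the other counts within 1.5 times. Of the named genes 37, 52 and 21 lost their call for hypoxia in control lungs, in knockout lungs and averaged, and of the lists 2 for hypoxia in control lungs, 1 in knockout lungs, 1 for knockout in hypoxia and 2 for knockout averaged. Of 15 pairs of arrays with the same number 4 correlated above 0.1 (median r = 0.021), and 2 of 12 arrays correlated best with an array of their own number, so the numbers do not pair the arrays.

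Without the 2 arrays with the highest Ucp1, 51 genes were called for hypoxia in knockout lungs, 0 for knockout in normoxia and 0 for the interaction, and Nfat5 for knockout in hypoxia was 0.0085. With the clock phase covariate the counts were 7, 0 and 0 for hypoxia in control lungs, in knockout lungs and averaged, 0 for knockout in normoxia and 0 for the interaction, with 8 lists for knockout averaged. Nfat5 was then -0.87 and -0.75 for hypoxia in control lungs and averaged, no longer passing.

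With the nuclear RNA covariate 2, 162 and 60 genes were called for hypoxia in control lungs, in knockout lungs and averaged, and 1 for knockout averaged. Nfat5 was -0.052 and -0.11 for hypoxia in control lungs and averaged, and -0.11 for the interaction, where its sign turned. Of the named genes called in control lungs 156 no longer passed, 4 turned sign and 2 kept their call, and in knockout lungs 49 kept it and 21 did not. Some of the 156 kept or gained size, such as Mmp2 (1.54 to 1.70), Fbln2 (1.08 to 1.15) and Lyve1 (-1.40 to -1.58). Others shrank, such as Bmpr2 (-1.03 to -0.09) and C1qc (1.01 to 0.14), so a lost call was not always a lost change. Signs also turned for Ccdc39 (0.24), Bag3 (-0.035), Hmox1 (-0.20) and Muc16 (0.23) in control lungs and H2-DMa (-0.064) averaged. The mean of the mitochondrial ribosome became -0.048 and that of MHC class II -0.18 in control lungs, and averaged MHC class II became -0.0068 and cardiac muscle 0.16. With the Malat1 and Neat1 covariate the counts were 0, 25 and 2, 1 for knockout averaged and 0 for the interaction, and Nfat5 turned sign, to 0.067, 0.0067 and 0.037 for hypoxia in control lungs, in knockout lungs and averaged, and -0.061 for the interaction.

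Leaving out 1 array at a time gave 808 to 3920 genes for hypoxia in control lungs, 71 to 258 in knockout lungs and 2254 to 4426 averaged. It gave 0 to 1 for knockout in normoxia, 0 to 1 in hypoxia, 0 averaged and 0 to 3 for the interaction. The lists called ranged over 17 to 24, 21 to 26, 19 to 27, 12 to 21, 7 to 14, 10 to 19 and 16 to 20 in the same order, and 1 array ended at most 7 of 24, 4 of 24, 4 of 22, 7 of 19, 8 of 13, 7 of 16 and 2 of 16 list calls. Nfat5 ranged from -0.77 to -0.54, -0.39 to -0.24 and -0.55 to -0.43 for hypoxia, from -0.53 to -0.30, -0.22 to 0.0085 and -0.33 to -0.19 for knockout, and from 0.21 to 0.45 for the interaction. For knockout in hypoxia its sign turned without control hypoxia 1 (0.0085) and without knockout hypoxia 2 (0.0020).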

Other observations

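Several genes of the endothelial, angiogenic and BMP lists, picked after their values were seen, changed in the same direction in both genotypes. Dll4 (-0.88 in control, -1.03 in knockout lungs), Efnb2 (-0.88 and -0.97) and Bmp6 (-1.02 and -1.12) fell, while Vegfc (0.92 and 0.94), Vegfd (0.61 and 0.69) and Mmrn1 (0.92 and 0.98) rose. Prox1, the regulator of lymphatic identity, was 0.95 ± 0.15 higher over both genotypes. Other genes of arteries, Notch signalling and lymphatics went the other way, with Fbln5 at 0.48 and 0.43, Hey2 at 0.80 and 0.58 and Lyve1 at -1.40 and -0.85. The arterial list did not pass in either genotype (adjusted p = 0.77 and 0.24). The interactions of Dll4 (-0.16), Efnb2 (-0.08), Bmp6 (-0.10), Vegfc (0.02), Vegfd (0.08) and Mmrn1 (0.06) did not pass, with SE between 0.15 and 0.21.

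Ntrk2 (3.23 and 2.98) and Gap43, a growth cone protein (1.56 and 0.86), rose in both genotypes, while the neural and ganglion list did not pass in either (adjusted p = 0.17 and 0.84). Adgre4, a receptor of monocytes, fell by 1.26 in control and 1.25 in knockout lungs (log2).

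For hypoxia averaged over genotypes, 1 of 100 splits of the arrays gave as many genes, the real one (3622, highest other 5). Chance can thus be excluded for the count of genes as far as these arrays go. The splits do not allow for the authors' choice of preparations, made partly on their response to hypoxia. For the lists, 10 of 100 gave as many (real 22, highest other 26), so chance cannot be excluded.

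For knockout averaged over oxygen states limma called 0 genes (1053 at an unadjusted p under 0.05), so all 100 of 100 splits have as many by construction and the count says nothing about chance. For its lists chance cannot be excluded (real 16, 26 of 100 splits with as many, highest other 22). The highest other split for genes called 672 and parts the 3 arrays with the highest nuclear RNA mean from the 3 with the lowest within each oxygen state. Both arrays with high Ucp1 (9.31 and 7.66) lie on its side of high nuclear RNA, and the 3 hypoxic arrays there are low in Y-linked genes. Nuclear RNA, adhering fat and sex therefore cannot be told apart in this split. This points to a structure of the samples other than genotype.

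The comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. For hypoxia in control lungs the real counts were 2839 genes and 24 lists, and the highest others 0 and 19, with 1 split as large in each case, the real one. In knockout lungs they were 282 genes and 24 lists, against 1 and 21, again with 1 split as large. For knockout in normoxia they were 1 gene and 19 lists, against 0 and 26, with 1 and 3 splits as large. For knockout in hypoxia they were 0 genes with limma (1259 at an unadjusted p under 0.05) and 13 lists, against 0 and 15, with 10 splits as large by construction for genes and 3 for lists.

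Ighg2b separated the 6 control from the 6 knockout arrays, as given above. Jchain was 0.96 ± 0.23 higher in knockout lungs over both oxygen states without passing.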
